A study of Homo sapiens with 6 samples.

How the data were processed

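RNA was measured in NCI-H1299 cells, an established human line that the labels describe as lung adenocarcinoma. The 6 libraries form 2 groups of 3, cells in which complement factor B was silenced (sh-CFB) and control cells (sh-NC), as the sample titles and the design text state. The names of the table's columns are of the kind used for siRNA, while the titles name short hairpins, so the form of the silencing reagent is not settled here and the group names of the design text are used. Total RNA was taken up in TRIzol and libraries were made with a stranded poly(A) kit, per the labels' protocols. No label says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

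The values are FPKM (fragments scaled to gene length and library size), made by the authors and deposited as a single table with 1 column per library. Every per-sample column of that table was used. Per the submitters' processing notes the tools were FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.3a and featureCounts 2.0.1 with the genome build GRCh38. The strand setting, the annotation release, the treatment of reads that fit several places and the FPKM formula are not given in the sources used here. A count table that the labels mention was not analysed here. With counting of this kind a gene that overlaps a neighbour or has a near-identical copy can lose or share reads, and a gene whose mRNA lacks a poly(A) tail is measured poorly by the library kit.

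The table held 28495 genes, of which 22492 had a gene symbol in the name table supplied with the reference, and no listed gene was at 0 in every library. Coordinates and gene type came from GENCODE 29 on GRCh38, as did GC content, taken from the longest transcript of each gene. Gene lengths were recovered together with the reads, and 86.8% of them lay within 10% of the annotated exon length. Because a whole number of reads lies behind each FPKM value, the value of 1 read and the total of each library could be recovered from the steps between low values. Reads came out whole within 0.02 for 99.97% of genes, and the recovered totals were 26.2, 33.4 and 38.4 M reads in sh-CFB replicates 1, 2 and 3 and 39.4, 40.0 and 32.9 M in sh-NC replicates 1, 2 and 3. In a gene of 2000 bases, 3 reads correspond to an FPKM of 0.0572 in the smallest library and 0.0375 in the largest. Floors and intervals from reads cover counting error only.

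Values were analysed as log2(FPKM + 0.5), for the 12466 genes with a mean FPKM of at least 0.5 over all 6 libraries. Fold changes are on that scale, which understates changes of low genes. The comparison used limma 3.58.1 in R 4.3.3 with an intensity trend and a moderated test, and Benjamini-Hochberg adjustment over all tested genes at 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, with the correlation estimated from the data as an alternative, and with fry, which tests whether a list's own genes move on balance and does not compare them with other genes. Fry was run only on the values as deposited, so its results carry any offset between the libraries. Lists needed at least 3 tested genes, and p-values were adjusted over the 30 lists that had them. Single genes below the filter were given as reads and FPKM per library with two-sided exact permutation tests, which cannot go below 0.1 with 3 libraries against 3. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining work.

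The groups, the tests, the gene lists and the first set of other settings were fixed before the data were examined. The lists were complement, AP-1 and immediate early, tryptophan metabolism, aryl hydrocarbon receptor, immune checkpoint and suppression, antigen presentation, interferon response, NF-kB and cytokines, cell cycle, cell cycle arrest and p53 targets, epithelial, mesenchymal and EMT, extracellular matrix and proteases, TGF-beta response, hypoxia and glycolysis, oxidative phosphorylation, sterol synthesis, fatty acid metabolism, ATF4 and amino acid response, unfolded protein response, heat shock, NRF2 and redox, apoptosis, MAPK and PI3K signalling, and YAP, WNT and NOTCH. Lists for RNA quality were protein-coding ribosomal, mitochondrial encoded, replication-dependent histones, and small nuclear and nucleolar RNA hosts and 7SK. Lists for cells that a culture could hold or lineages it could show were immune cells, fibroblasts, endothelial cells, erythroid cells, lung epithelial lineage and neuroendocrine.

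The genes chosen for description, some of which are left out of the text, were CFB, FOS, IDO1 and TDO2; the 10 highest and 10 lowest log2 fold changes among genes past the test with a mean FPKM of at least 2 in the higher group and no overlap between groups, passing over rows without a symbol, pseudogenes, small RNA and clone-based names; and in each list up to 2 changed members per direction or, in a list with none, the tested member with the highest mean FPKM. IDO1 was looked up by its symbol and was not found among the listed genes, so no value is given for it. Other list members named to complete a small count were chosen after their values were seen, as were the genes said to be so in the text.

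The other settings fixed at that point were pseudocounts of 0.1 and 1, no filter and a filter at a mean FPKM of 5, values rescaled to equal totals (the stand-in for a TPM scale, kept at the mean total so that the pseudocount stayed comparable), median-of-ratios factors, quantile normalization, limma without the trend and with robust estimation, the replicate number as a block, each library left out in turn, an adjusted p of 0.01 and the estimated correlation. A smooth correction of each library for GC content and gene length (99.4% of tested genes had both), with and without the block or a replicate 1 library, the omission of both replicate 1 libraries, limma's voom on the recovered reads and thinning of reads to the smallest library were added after seeing the data.

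The fit was tested on simulated data for the same 12466 genes, with 67 genes each changed 1.5-fold and 2-fold and 66 changed 4-fold. It recovered 1.49% of the 1.5-fold, 23.9% of the 2-fold and 93.9% of the 4-fold changes, with 3 false calls among unchanged genes. With no change put in, it made 0 calls of genes and 0 of lists. In the real libraries, each other split into groups of 3 gave 4 to 12 lists past camera. The simulated 0 is therefore not a rate of false list calls for these data.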

Results

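The study compared mRNA of NCI-H1299 lung adenocarcinoma cells silenced for complement factor B with that of control cells, in 3 libraries each. The line is known to lack p53. CFB encodes factor B, which supplies the protease of the C3 convertase in the alternative complement pathway. The design asks which transcripts differ when CFB is silenced, and the series title points to FOS, tryptophan metabolism and immune suppression. Recovered depth ran from 26.2 M (M, 1e6) reads in sh-CFB replicate 1 to 40.0 M in sh-NC replicate 2. Correlations of log2 values across genes lay between 0.975 and 0.991 within groups and between 0.95 and 0.982 across groups.

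The libraries also differed along an axis that was not the group alone. The first principal component held 56.6% of the variance, with sh-CFB replicate 1 at one end (-0.74) and sh-NC replicate 1 at the other (0.60). Across genes, which are not independent replicates, each library's deviation from the gene mean had a Spearman correlation with GC content of 0.60, -0.10 and -0.16 in sh-CFB replicates 1, 2 and 3 and of -0.55, -0.25 and 0.23 in sh-NC replicates 1, 2 and 3. The median tested gene stood at a log2 fold change of -0.15, and median-of-ratios factors moved that median by 0.16 to 0.02. For some lists below the median is therefore also given relative to the median tested gene.

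CFB itself was close to undetected in both groups. The gene (ENSG00000243649) lies on chromosome 6 from 31945650 to 31952084 on the forward strand. Its FPKM was 0, 0 and 0.0110 in the sh-CFB libraries, which held 0, 0 and 2 reads, and 0.00536, 0.0317 and 0.0321 in the sh-NC libraries, which held 1, 6 and 5 reads. An FPKM of 0.0158 to 0.0242, depending on the library, corresponds to 3 reads. Pooled over libraries, 2 reads among 98.0 M in sh-CFB stood against 12 among 112.4 M in sh-NC, a ratio of rates of 0.191 with an exact 95% counting interval from 0.0208 to 0.858. Over libraries the groups overlapped, with a two-sided exact permutation p of 0.2. On the log2(FPKM + 0.5) scale the difference was -0.05. At this depth the target gene gave no check of the labels library by library.

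FOS, which encodes a subunit of the AP-1 transcription factor, rose in sh-CFB. It lies on chromosome 14 from 75278774 to 75282230. Its FPKM was 10.2, 13.5 and 25.3 in sh-CFB and 4.06, 3.93 and 4.33 in sh-NC, with means of 16.3 ± 7.93 and 4.10 ± 0.203 (SD, n = 3 each). The fitted difference was 1.77 on the log2 scale (SE 0.29, adjusted p = 0.0160 with limma), or 3.41-fold. FOS was higher in 3 of 3 sh-CFB libraries than in any sh-NC library, with a two-sided exact permutation p of 0.1, the smallest possible. Without sh-CFB replicate 2 its adjusted p was 0.0622, and without sh-NC replicate 2 it was 0.0879, with log2 fold changes of 1.85 and 1.74.

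Other immediate early genes moved in part with FOS. In the AP-1 and immediate early list, 4 of 31 tested members rose, 1 fell and 26 did not pass the test. Adjusted over the list alone, 5 rose and 2 fell, and after the GC and length correction 8 rose and 1 fell. DUSP1, a phosphatase that switches off MAP kinases, rose from 24.6 ± 2.7 to 58.1 ± 7.40 FPKM (SD, n = 3 each), a log2 change of 1.22 (SE 0.13, adjusted p = 0.00753). NR4A2 (0.82) and ZFP36 (0.69), named after their values were seen, rose as well, and CCN2, a matricellular growth factor, fell by 0.50 (adjusted p = 0.0463). After the GC and length correction CCN2 did not pass (-0.29, adjusted p = 0.0892). The member that fell there was KLF2 (-0.75, adjusted p = 0.00650), named after its values were seen. JUN (0.54, adjusted p = 0.241), JUNB (0.28, adjusted p = 0.131) and EGR1 (0.91, adjusted p = 0.283), also named after their values were seen, did not pass. The list median was 0.17, or 0.32 relative to the median tested gene; after the GC and length correction it was 0.12, with the median tested gene at 0.01. Camera placed the list above other genes (adjusted p = 0.000168, and 0.0157 after that correction), while the adjusted p = 0.448 with an estimated correlation and fry did not call the list (adjusted p = 0.436).

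Tryptophan metabolism, the other pathway in the title, held genes that fell and none that rose. Of 21 tested members 5 fell and 16 did not pass; adjusted over the list alone, 12 fell. WARS1, the cytosolic tryptophanyl-tRNA synthetase, went from 28.0 ± 5.40 FPKM in sh-NC to 10.3 ± 0.552 in sh-CFB (SD, n = 3 each), a log2 change of -1.39 (SE 0.15, adjusted p = 0.00778). SLC7A5, the large neutral amino acid carrier that takes up tryptophan, went from 80.5 ± 18.5 to 31.3 ± 1.41 FPKM, a change of -1.32 (SE 0.17, adjusted p = 0.0106). The remaining members that fell were ACAT2, ALDH9A1 and HADHA, enzymes shared with fatty acid, sterol or aldehyde metabolism, at -0.88, -0.69 and -0.56. These members load tRNA, carry amino acids or act in general catabolism, and none starts the kynurenine branch. TDO2, which does, had an FPKM of 0 in all 3 sh-CFB libraries and 0.00963, 0.00949 and 0 in sh-NC, or 4 reads in all. IDO1 was not found among the listed genes. The list median was -0.42, or -0.28 relative to the median tested gene, with a camera adjusted p = 0.000168, an adjusted p = 0.402 with an estimated correlation and a fry adjusted p = 0.0190. In the aryl hydrocarbon receptor list, which collects targets of a receptor that binds tryptophan products, 1 of 8 tested members fell and 7 did not pass, and the same count fell adjusted over the list alone. The member that fell was NQO1, a quinone reductase (-0.40, adjusted p = 0.0349), which stood at -0.11 (adjusted p = 0.561) after the GC and length correction, where 0 members fell; the camera adjusted p was 0.817.

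Genes of immune suppression and immune recognition changed little and in mixed directions. In the immune checkpoint and suppression list, 1 of 16 tested members rose, 0 fell and 15 did not pass; adjusted over the list alone, 2 rose and 1 fell. The member that rose was HLA-E, a non-classical class I molecule that engages an inhibitory receptor on natural killer cells, from 141.7 ± 6.25 to 196.3 ± 4.64 FPKM (SD, n = 3 each; log2 change 0.47, SE 0.09, adjusted p = 0.0220). Camera gave this list an adjusted p = 0.0217, upward, and the adjusted p = 0.402 with an estimated correlation. Its median was 0.03, or 0.18 relative to the median tested gene. The median was -0.02 when FPKM was rescaled to equal totals, 0.21 with median-of-ratios factors and 0.20 after the GC and length correction. After that correction 2 members rose and 0 fell (camera adjusted p = 0.0401). With median-of-ratios factors the camera adjusted p was 0.0796. In antigen presentation, 2 of 18 members rose, 1 fell (PDIA3, an endoplasmic reticulum thiol oxidoreductase, -0.63) and 15 did not pass, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.0879). In the interferon response, 1 of 22 rose (ISG15, a ubiquitin-like protein, 0.82), 1 fell (IFI35, -0.48) and 20 did not pass, with the same counts adjusted over the list alone. Its camera adjusted p was 0.0935, 0.0439 upward after the GC and length correction, and 0.521 with an estimated correlation on uncorrected values. In NF-kB and cytokines, 1 of 22 rose (BCL3, a nuclear IkB protein, 0.74) and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0763). None of the 8 tested members of the complement list changed, also when adjusted over the list alone (camera adjusted p = 0.487). Its most abundant member, CFD, the protease that cleaves factor B, had a log2 difference of 0.70 (adjusted p = 0.0843).

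**Figure D1:**
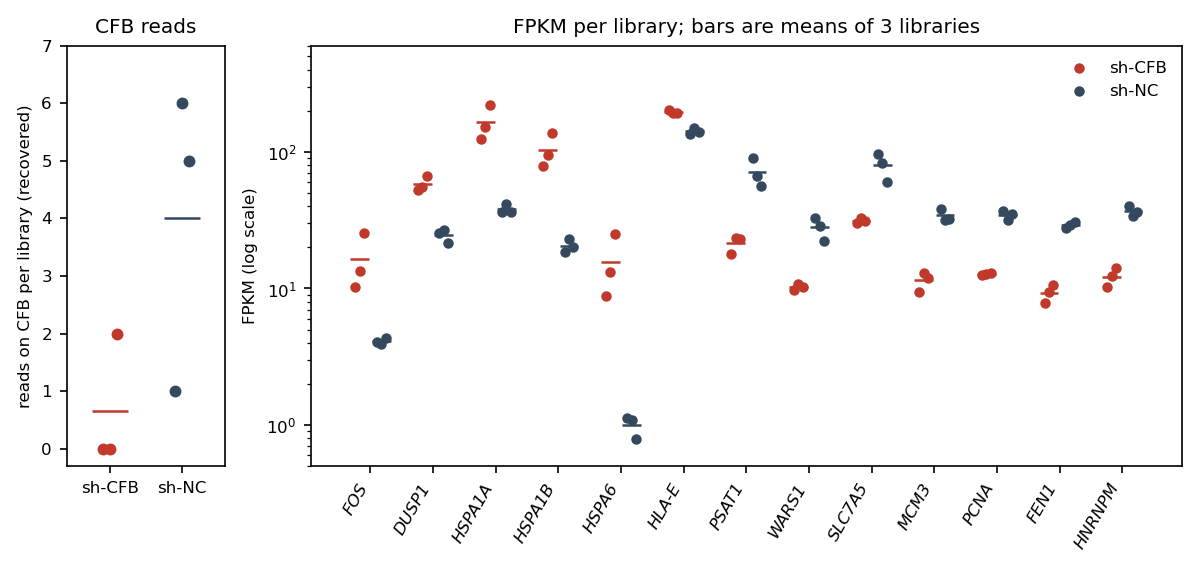
Left, reads on CFB in each library, with bars at group means. Right, FPKM of 13 named genes in each of the 3 sh-CFB (red) and 3 sh-NC (dark) libraries on a log axis, with bars at group means: CFB held at most 6 reads in any library, and for the other genes shown no library of one group lies within the range of the other.

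Across all tested genes, 929 changed, 217 higher and 712 lower in sh-CFB, and 89 of these changed at least 2-fold, 17 higher and 72 lower. Groups did not overlap for 4195 genes, or 33.7% of those tested. Chance gives 10% on average over all splits of the libraries, but genes move together, so a single split can lie far from it. The share was not computed for the other splits. The share of changed genes that were higher was 23.4%. After median-of-ratios factors the counts were 68 higher and 138 lower, after quantile normalization 465 and 636 (42.2% higher), after voom with median-of-ratios factors 124 and 190 (39.5%), and after the GC and length correction 613 and 764 (44.5%). The balance of genes changed at least 2-fold depended on the scaling. It turned after median-of-ratios factors (27 higher and 24 lower), quantile normalization (42 and 32) and voom with median-of-ratios factors (53 and 43). It stayed on the lower side after the GC and length correction (25 higher and 38 lower), rescaling to equal totals (15 and 96) and voom without those factors (25 and 112). Median GC content was 60.9% for the genes that were higher, 49.0% for those that were lower and 49.3% over all tested genes. The count depended on single libraries: it was 511, 39 and 400 without sh-CFB replicates 1, 2 and 3 and 249, 20 and 540 without sh-NC replicates 1, 2 and 3. Without both replicate 1 libraries 694 genes changed. No gene among the 929 changed sign in any of these settings. The settings reuse the libraries in which these genes were chosen, so a change of sign was unlikely from the start. Of 30 gene lists 12 passed the camera test, 7 upward and 5 downward, and 0 passed with an estimated correlation.

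The 10 highest named genes were led by the stress-inducible HSP70 genes. HSPA6 (chromosome 1 from 161524540 to 161526910) went from 0.996 ± 0.183 to 15.6 ± 8.36 FPKM (SD, n = 3 each), a log2 change of 3.31 (SE 0.34, adjusted p = 0.00727). HSPA1B (chromosome 6 from 31827735 to 31830255) went from 20.4 ± 2.24 to 103.7 ± 29.6 FPKM, a change of 2.28 (SE 0.19, adjusted p = 0.00613), and HSPA1A (31815464 to 31817946) from 38.1 ± 2.99 to 164.9 ± 49.9 FPKM, a change of 2.06 (SE 0.20, adjusted p = 0.00727). HSPA1A and HSPA1B are near-identical copies, so how reads fell between them is uncertain. FOS and DUSP1 were also among the 10, and the other 5 were BAIAP3 (1.31), the zinc finger gene ZNF581 (1.17), the potassium channel subunit KCNF1 (1.16), the histone gene H2AC25 (1.13) and DBP, a circadian PAR bZIP transcription factor (1.12).

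Of the 10 lowest genes, 9 are described here. They included a splicing regulator, genes of DNA replication, an enzyme of serine synthesis and tRNA synthetases, a grouping made after the values were seen. HNRNPM, a splicing regulator, changed by -1.56 (adjusted p = 0.00613). FEN1, the flap endonuclease, changed by -1.61, the replicative helicase subunits MCM3 and MCM4 by -1.55 and -1.41, and PCNA, the sliding clamp, by -1.40 from 34.5 ± 2.48 to 12.7 ± 0.215 FPKM (SD, n = 3 each; adjusted p = 0.00377). PSAT1, an enzyme of serine synthesis, changed by -1.69, AARS1, the alanyl-tRNA synthetase, by -1.47, CHAC1, which degrades glutathione, by -1.40, and WARS1 by -1.39. Among the genes described, HSPA6, HSPA1A, HSPA1B, DUSP1, FEN1, HNRNPM, MCM3, MCM4 and PCNA passed the test under every alternative without the replicate block. Over all 62 changed genes chosen for description other than FOS, 51 still passed after the GC and length correction (all but CCN2, NQO1, TPM1, COL6A2, LTBP4, PFKL, LDHA, ATP5F1A, FABP5, TKT and BBC3), 10 without sh-NC replicate 2 and 15 without sh-CFB replicate 2.

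Cell cycle genes fell together. Of 49 tested members 29 fell, 0 rose and 20 did not pass; adjusted over the list alone, 34 fell. MCM3 went from 34.2 ± 3.60 to 11.4 ± 1.81 FPKM and MCM4 from 28.2 ± 3.04 to 10.3 ± 1.63 (SD, n = 3 each; adjusted p = 0.00669 and 0.00727). The list median was -0.72, or -0.58 relative to the median tested gene, and -0.50 after the GC and length correction, where 27 members fell. Camera gave an adjusted p = 6.94e-15, and the adjusted p = 0.402 with an estimated correlation; fry, which called 4 of the 30 lists, gave an adjusted p of 0.00959. In the list of cell cycle arrest and p53 targets, 4 of 24 rose, 1 fell and 19 did not pass, and adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.109). CDKN1C, a CDK inhibitor, rose by 0.92 and GADD45B, a stress sensor, by 0.70, as did CDKN2A (0.59) and BBC3 (0.56), while SESN2, also a target of ATF4, fell by 1.16 (adjusted p = 0.0330).

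Genes of amino acid supply and protein folding in the endoplasmic reticulum fell as well. In the ATF4 and amino acid response list, 12 of 30 tested members fell, 0 rose and 18 did not pass; adjusted over the list alone, 22 fell. PSAT1 went from 71.2 ± 17.4 to 21.4 ± 3.02 FPKM and CHAC1 from 8.53 ± 1.16 to 2.91 ± 0.422 (SD, n = 3 each; adjusted p = 0.00788 and 0.00839). Within sh-NC, PSAT1 stood at 90.4, 66.7 and 56.4 FPKM in replicates 1, 2 and 3, highest in the library at the end of the first principal component. The list median was -0.61, or -0.46 relative to the median tested gene (camera adjusted p = 2.17e-09, and adjusted p = 0.402 with an estimated correlation; fry adjusted p = 0.0484), and 13 members fell after the GC and length correction. In the unfolded protein response, 8 of 21 fell and 13 did not pass; adjusted over the list alone, 13 fell. HERPUD1, a factor of protein degradation at the endoplasmic reticulum, changed by -1.14 and the chaperone HYOU1 by -1.07 (adjusted p = 0.0122 and 0.0189), and 5 members fell after the GC and length correction. Its median was -0.43, or -0.29 relative to the median tested gene (camera adjusted p = 2.37e-05, and adjusted p = 0.407 with an estimated correlation), and fry did not call it (adjusted p = 0.102).

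**Figure D2:**
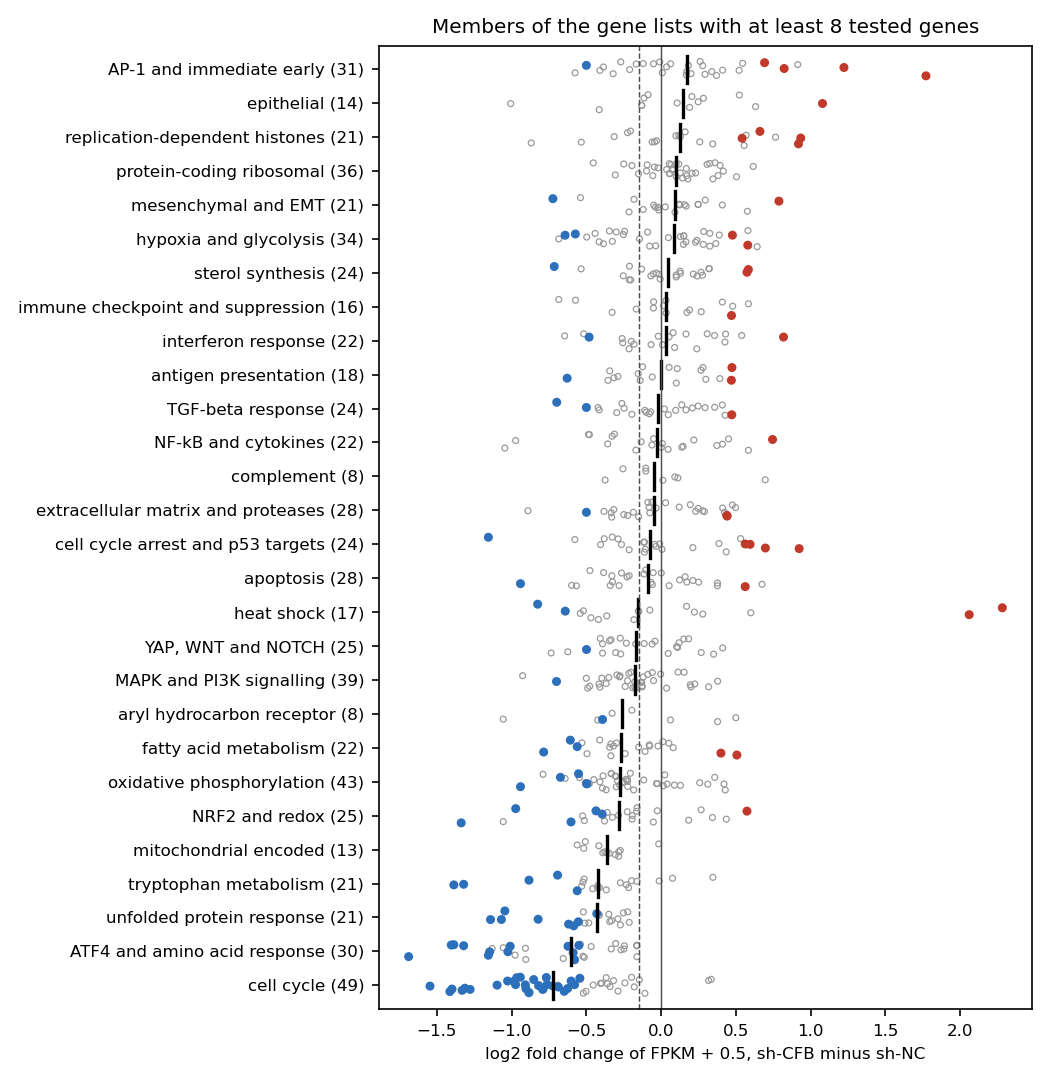
Log2 fold change of each tested member of the lists with at least 8 tested genes (number in brackets), with members past the test filled in red (higher) or blue (lower) and others open. Thick bars are list medians and the dashed line is the median tested gene at -0.15: of these lists, all fixed before the data were examined, the cell cycle list lies lowest, with a median of -0.72.

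Chaperones of the cytosol split. In the heat shock list 2 of 17 members rose (HSPA1A and HSPA1B), 2 fell and 13 did not pass; adjusted over the list alone, 3 rose and 4 fell. The members that fell were the co-chaperone DNAJA1 (-0.83, adjusted p = 0.0273) and HSP90AB1, a constitutive HSP90 (-0.64, adjusted p = 0.0257). The list median was -0.15, which became 0.02 with median-of-ratios factors, and its mean 0.07, and camera did not separate it from other genes (adjusted p = 0.583). In NRF2 and redox, 1 of 25 rose (TKT, a pentose phosphate enzyme, 0.57), 5 fell (TXNRD1 at -1.34, HMOX1 at -0.97, PRDX1, PGD and NQO1) and 19 did not pass, with the same counts adjusted over the list alone. After the GC and length correction 0 rose and 3 fell, and the list median went from -0.29 to -0.08. The camera adjusted p was 0.120, while fry, on values whose median tested gene stood at -0.15, called the list downward (adjusted p = 0.0118).

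Metabolic lists showed smaller changes. In oxidative phosphorylation, 5 of 43 members fell (CYCS, the electron carrier, at -0.94, ATP5F1A, an ATP synthase subunit, at -0.67, and UQCRFS1, SDHB and SDHC) and 38 did not pass; adjusted over the list alone, 9 fell. Its camera adjusted p was 0.0217, and the adjusted p = 0.558 with an estimated correlation. After the GC and length correction 2 members fell and the camera adjusted p was 0.195. In hypoxia and glycolysis, 2 of 34 rose (PFKL at 0.58 and ENO2 at 0.48), 2 fell (PGAM1 at -0.64 and LDHA at -0.57, all glycolytic enzymes) and 30 did not pass, and after the GC and length correction PFKL (0.44, adjusted p = 0.0531) and LDHA (-0.29, adjusted p = 0.230) did not pass either. Adjusted over the list alone, 6 rose and 4 fell. The camera adjusted p was 0.0699, and 0.0289 upward after the correction. With an estimated correlation, run on uncorrected values only, it was 0.619. In sterol synthesis, 2 of 24 rose (TM7SF2 at 0.58 and the regulator SREBF1 at 0.57), 1 fell and 21 did not pass, also adjusted over the list alone. Here the camera adjusted p was 0.0635, 0.0157 upward after the correction, and 0.521 with an estimated correlation on uncorrected values. In fatty acid metabolism, 2 of 22 rose (ACSS2 at 0.51 and ACADVL at 0.40), 3 fell (ACLY at -0.79, FABP5 at -0.61 and HADHA) and 17 did not pass; adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.263).

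Lists of cell identity, matrix and signalling held few changed genes. In the epithelial list 1 of 14 rose (TJP3, a tight junction scaffold, 1.07) and 13 did not pass; adjusted over the list alone, 2 rose. In mesenchymal and EMT, 1 of 21 rose (S100A4, 0.79), 1 fell (TPM1, a tropomyosin, -0.72) and 19 did not pass, also adjusted over the list alone. Extracellular matrix and proteases had 2 of 28 members that rose (COL6A2 and LAMB3, both at 0.44), 1 that fell (CCN2) and 25 that did not pass; adjusted over the list alone, 4 rose and 2 fell. Camera gave these lists adjusted p-values of 0.0217, 0.0202 and 0.0217, upward, and adjusted p = 0.402, 0.402 and 0.619 with an estimated correlation. The epithelial and matrix calls were also lost after the GC and length correction (0.195 and 0.0630). In the TGF-beta response 1 of 24 rose (LTBP4, 0.47), 2 fell (ID1, an inhibitor of bHLH factors, -0.70, and CCN2) and 21 did not pass; adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.0988). In apoptosis 1 of 28 rose (BBC3), 1 fell (CYCS) and 26 did not pass, also adjusted over the list alone (camera adjusted p = 0.583). In MAPK and PI3K signalling 1 of 39 fell (ETV5, an ETS factor, -0.70) and 38 did not pass, and in YAP, WNT and NOTCH 1 of 25 fell (CCN2) and 24 did not pass; adjusted over the list alone, 0 members of either list changed (camera adjusted p = 0.655 and 0.817). Camera compares a list with other genes, so its direction was upward for the matrix list at a median of -0.05 and a mean of 0.01, and also, without a call, for the complement, antigen presentation, NF-kB, arrest and p53, TGF-beta, apoptosis, heat shock, and YAP, WNT and NOTCH lists, whose medians lay below 0.

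Lists that track RNA quality moved with the groups in part. Reads on ribosomal protein genes made up 18.9%, 17.7% and 17% of reads in sh-CFB replicates 1, 2 and 3 and 13.9%, 14.9% and 16.1% in sh-NC replicates 1, 2 and 3. None of the 36 tested protein-coding ribosomal genes changed, also when adjusted over the list alone; RPL8, the most abundant, differed by 0.39 (adjusted p = 0.198). Their median was 0.10, or 0.25 relative to the median tested gene (camera adjusted p = 0.000168, and adjusted p = 0.402 with an estimated correlation). After the GC and length correction 3 of these genes rose and 0 fell. Their median was then 0.27, with the median tested gene at 0.01 (camera adjusted p = 1.44e-06). Of 21 replication-dependent histones 4 rose (H2BC21 at 0.93, H1-2 at 0.92, H2BC5 at 0.66 and H2AC6 at 0.54) and 17 did not pass, also adjusted over the list alone (camera adjusted p = 0.000619, and adjusted p = 0.510 with an estimated correlation). None of the 13 mitochondrial encoded genes changed, also when adjusted over the list alone (MT-CO2 -0.36, adjusted p = 0.372; camera adjusted p = 0.0847). None of 7 small nuclear and nucleolar RNA hosts and 7SK changed, and 1 fell adjusted over the list alone (camera adjusted p = 0.0935); RN7SL1 stood at 838.1 FPKM in sh-CFB replicate 1 and between 122.1 and 263.3 in the other libraries.

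Markers of other cells were low. None of 8 endothelial and 3 erythroid markers listed reached a mean FPKM of 0.5, and 2 of 15 immune cell markers (ITGAM at 0.665 and CD79A at 0.608 FPKM), 1 of 7 fibroblast markers (ACTA2 at 0.622) and 1 of 14 lung epithelial lineage genes (AGER at 1.16) did; 0 of these changed, also when adjusted over the list alone. Among neuroendocrine genes 1 of 4 tested rose, ENO2, an enolase also held by the glycolysis list, and 3 did not pass, also adjusted over the list alone (camera adjusted p = 0.0935).

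**Figure D3:**
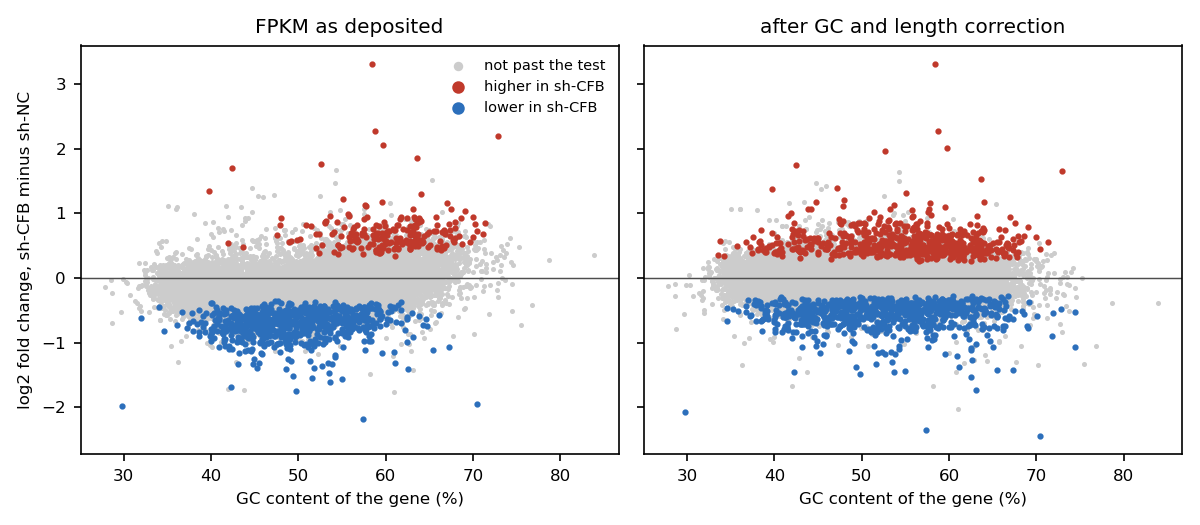
Log2 fold change of each tested gene against the GC content of its longest annotated transcript, from FPKM as deposited (left) and after the GC and length correction (right), with changed genes in red (higher) and blue (lower). Higher genes had a median GC content of 60.9% and lower genes of 49.0% in the values as deposited, and the counts became 613 higher and 764 lower after the correction.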

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

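The GC and length correction in all its forms, the omission of both replicate 1 libraries, voom on recovered reads and thinning were chosen only after the results were seen. All other settings were planned. FOS stayed higher in all 24 alternatives, with log2 fold changes from 1.41 to 2.20 and adjusted p from 0.00903 to 0.148. It missed the threshold with no filter (1.77, adjusted p = 0.0653) and without sh-CFB replicate 2 or sh-NC replicate 2 (0.0622 and 0.0879); leaving out each library in turn gave 1.41 to 2.05. With no filter more genes enter the adjustment; the cause of the other losses was not tested. CFB moved from -0.05 to -0.24 with a pseudocount of 0.1, which weighs values near 0 more, and lay between -0.08 and -0.04 with each library left out. Without a filter its p was 0.151 (adjusted p = 0.570). Quantile normalization, the GC and length correction, voom and thinning gave no value for CFB.

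Against 929 changed genes, the count was 324 with no filter, 206 with median-of-ratios factors, 531 without the intensity trend, 49 at an adjusted p of 0.01, 581 with the GC and length correction without sh-NC replicate 1, 314 with voom and median-of-ratios factors, and from 20 (without sh-NC replicate 2) to 540 (without sh-NC replicate 3) with each library left out. Fewer samples go into the last settings and a stricter limit into the fourth; the cause of the other moves was not tested. Against 89 genes changed at least 2-fold, the count was 141 with a pseudocount of 0.1, 51 with median-of-ratios factors, 52 and 49 with the GC and length correction without sh-CFB replicate 1 and without sh-NC replicate 1, 137 with voom, and from 20 to 129 with each library left out. Of the 929 genes, 678 also passed after the GC and length correction and 187 after median-of-ratios factors, all in the same direction.

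Gene lists past the camera test numbered 12, and 8 to 18 in every other setting except the estimated correlation, where 0 passed. Over these 12 lists that correlation ran from -0.0117 in mesenchymal and EMT to 0.447 in extracellular matrix and proteases, against the preset of 0.01. A value above the preset therefore does not describe every loss. The adjusted p with an estimated correlation thus does not reflect the correlation between genes alone. For the 69 tested genes chosen for description other than CFB and FOS, 1648 values under other settings held 0 reversals, 1112 on the same side of the threshold, 535 no longer past it (124 of these with the replicate block) and 1 newly past it, CFD after the GC and length correction (0.45, adjusted p = 0.0452). Most of these genes were chosen because they passed in the same libraries, so reversals were unlikely from the start.

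No label says that the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.54, 0.07 and -0.45, and of the 6 libraries sh-NC replicate 2 alone correlated best with its own number. The libraries also differ along the GC and length gradient, which can set these correlations, so they do not decide whether the samples were paired. With the replicate number as a block, limma called 0 genes, 0 of them at least 2-fold, with 1770 at an unadjusted p under 0.05, and FOS kept a log2 fold change of 1.77 (adjusted p = 0.148). With the block and the GC and length correction the counts were again 0 and 0, with 2441 at an unadjusted p under 0.05, and FOS stood at 1.96 (adjusted p = 0.101).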

Other observations

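The tests chosen only after the result was seen were those on the 6 gene lists added for the next 2 paragraphs, S phase against G2 and M genes, the other heat shock genes, CFB reads against depth, the GC and length correction, thinning, and the omission of both replicate 1 libraries.

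Several cytosolic enzymes that load amino acids onto tRNA fell; their list holds AARS1 and WARS1, which prompted it, and so is not independent evidence. Of 20 tested cytosolic aminoacyl-tRNA synthetases 11 fell and 0 rose, with a median log2 fold change of -0.73 and of -0.47 after the GC and length correction, where 12 fell and 1 rose (camera adjusted p = 1.41e-07 over the 6 lists added here, of which 5 are described, and adjusted p = 0.228 with an estimated correlation). Of 16 mitochondrial synthetases 4 fell, with a median of -0.36 (camera adjusted p = 0.00300, 0.0195 after the correction and 0.231 with an estimated correlation). After the correction the median was -0.13, which does not decide whether both compartments fell. The tryptophan list without WARS1, SLC7A5 and SLC3A2, the genes it shares with the amino acid response list, still lay below other genes (3 of 18 fell, camera p = 0.00114, and p = 0.190 with an estimated correlation), so at the preset correlation those 3 genes were not the whole of its shift.

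Within the cell cycle list, S phase genes fell further than G2 and M genes. Of 22 S phase genes 19 fell, at a median of -0.96, and of 25 G2 and M genes 9 fell, at a median of -0.50 (camera adjusted p = 2.58e-15 and 4.38e-06 over the added lists, and adjusted p = 0.0765 and 0.228 with an estimated correlation). After the GC and length correction the mean of S phase genes minus that of G2 and M genes was -1.02 ± 0.00800 in sh-CFB and -0.54 ± 0.0811 in sh-NC (SD, n = 3 each), a difference of -0.48 with no overlap between groups and a two-sided exact permutation p of 0.1, the smallest possible. A lower share of cells in S phase is a hypothesis that may account for this. Among replication-dependent histones, also bound to S phase, 4 of 21 rose and 0 fell (camera adjusted p = 0.000619, and 0.510 with an estimated correlation). After the correction 4 rose and 1 fell (camera adjusted p = 0.0438). Most of their mRNA lacks a poly(A) tail, and how far these poly(A) libraries count it was not tested. The histone values therefore cannot decide for or against the hypothesis, which stays open. Lower transcription of the S phase genes per cell gives the same values, and no measure of DNA content was used.

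CFB was low in all libraries and lower in sh-CFB. Of its 4997 exon bases, taken over all annotated transcripts, 45.5% lie in same-strand exons of C2 or a readthrough gene in GENCODE 29. This leaves 2725 bases annotated for CFB alone. How much of the mature CFB mRNA lies in those bases was not tested. Lost overlapping reads may therefore lower the level in both groups by an unknown amount. Among protein-coding genes, 98.9% of 475 with at least 90% shared bases had a mean FPKM under 0.1, against 53.4% of 161 genes with a share like that of CFB and 35.7% of 19043 genes with under 50%. Depth alone would place 6.52 of the 14 reads in sh-CFB, where 2 were found (two-sided exact binomial p = 0.0158, counting error only). Open points are the authors' annotation, which is not given in the sources used here, and the spread between libraries, over which the permutation p was 0.2.

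More genes fell than rose, and genes of replication and amino acid supply led the fall. After the GC and length correction 44.5% of changed genes were higher, but that correction also centres the libraries, and settings that centre them without it gave 33.0% (median-of-ratios factors), 39.5% (voom with these factors) and 42.2% (quantile normalization), so a part of the gradient in the excess of lower genes cannot be told apart from centring. Smaller sh-CFB libraries do not explain it, with 23.5% higher after thinning to the smallest total. The gradient is not the whole cause of the fall of replication and amino acid genes, as 37 of the 41 changed members of those lists passed after the correction, and 37 of 41 passed without both replicate 1 libraries, the ends of the first principal component. An effect of CFB silencing, and a difference in growth or density between cultures that no label records, were not tested against each other.

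HSPA1A, HSPA1B and HSPA6 rose far more than other chaperones. The median over the remaining 15 members of the heat shock list was -0.18 (SD 0.393), close to the median tested gene at -0.15. Of these, DNAJB1 was at 0.60 (adjusted p = 0.0736 with limma) and passed after the GC and length correction (0.79, adjusted p = 0.0159). The remaining members include constitutive chaperones such as HSP90AB1, so their median cannot tell whether a general heat shock response occurred. HSPA1A and HSPA1B lie within 1 Mb of CFB, but 2 of 47 other tested genes in that window changed (NFKBIL1 and TCF19, in opposite directions) against 925 of 12417 elsewhere (one-sided Fisher exact p = 0.874). On simulated data the fit recovered 93.9% of 4-fold, 23.9% of 2-fold and 1.49% of 1.5-fold changes. The count therefore argues against a 4-fold change of the whole region, but it cannot decide on a smaller one. HSPA6 lies on chromosome 1. Reads shared between HSPA1A and HSPA1B could shift counts from one to the other but not raise both. What raised these genes was not tested further.

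The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. With limma the real split gave 929 changed genes, 89 of them at least 2-fold, and the highest of the other splits gave 0 and 0, with up to 1870 genes at an unadjusted p under 0.05 against 3225 in the real split. For gene lists past the camera test the real split gave 12, and the highest other split also gave 12 (sh-CFB replicates 1 and 3 with sh-NC replicate 1 against the rest).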
